A study of Mus musculus with 34 samples.

How the data were processed

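RNA was measured in 34 libraries from the hippocampus of mice given fluoxetine or vehicle: granule cells (4 vehicle, 4 fluoxetine), mossy cells (6 and 7) and hippocampus (6 and 7). Per the labels, RNA came from translating ribosome affinity purification and a micro column kit, cDNA was made from 500 pg of RNA with a single-primer amplification kit, and libraries were read as 50 bp pairs. Per the submitters' processing notes, STAR 2.5.2b, HTSeq 0.7.2 and edgeR were used with the GRCm38 build. The notes do not give the annotation, the strand setting or the handling of reads that align to several places. The deposited values are counts, which the authors give as raw read counts per gene symbol, in 3 tables, 1 per source. Every value was checked to be a whole number, and no sample column was left out. Each table holds 24485 symbols, of which 22753 were matched directly to GENCODE M21 and 1322 through 1 RefSeq synonym, for positions, transcript GC content and length. Total counts per library, which set the precision of each value, ranged from 14.1 to 45 M. PCR duplicates cannot be removed from such tables, so counts are not independent molecules.

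Groups were taken from the labels. The comparisons, the tests, the rule for the genes named, 34 gene lists and the first set of alternatives were fixed before the data were examined. Each fluoxetine comparison was fitted within its own 2 groups with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, estimateDisp, glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Mossy cells and hippocampus were fitted together over 26 libraries, and granule and mossy cells over 21, with 4 group means each. These fits gave the vehicle contrast between sources and the interaction, which is the difference between their fluoxetine effects. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists with at least 3 tested members within a comparison, which was 33 of 34. The list of mitochondrially encoded genes had 0 members in the tables. Members were counted after adjustment over all genes and after adjustment over the list alone. The lists are short, overlap in part (Vgf is a neuropeptide and a granin, Sst a neuropeptide and an interneuron marker), and hold genes that other hippocampal cells express.

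Genes were named by rule. The rule took up to 8 higher and 8 lower genes with the largest change among those past the threshold, with an average log2 CPM of at least 3, the same sign in every fit without 1 library, and a name other than a clone or predicted gene. It added up to 4 called members of each list by smallest p, 19 genes always, and the 5 smallest p where fewer than 5 genes passed. For interactions and contrasts between sources the numbers were 5 per direction and 2 per list. Not every gene that the rule took has its value in the text, and some withheld for evaluation are not reported here. Drd1 stands as Drd1a in the tables. Uvssa, A130077B15Rik, Il1r1, Cartpt, Gfap and Psap in granule cells lie outside the rule. Means and SDs of CPM use TMM-scaled library sizes, and standard errors are those of the fitted log2 change.

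That first set of alternatives held DESeq2 size factors, upper quartile scaling, no filter, a mean CPM of at least 5, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, robust glmQLFit, replicate number as a block, 1 surrogate variable (sva 3.50.0), an adjusted p of 0.1, a spread shared over 26 libraries, an estimated correlation for camera, and each library left out in turn. After seeing the data, the following were added: removal of Rn45s and Lars2, a correction for transcript GC content and length (a loess offset per library, span 0.3), a term for the granule-cell libraries with low against high Rn45s share, a replicate block for the granule and mossy-cell fits, and removal of sets of libraries that stood apart. A value of DESeq2 that its filter set to missing stayed missing.

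The edgeR fit of each comparison was tested on simulated data made from the same libraries, as were DESeq2, limma-voom and the block in the 3 fluoxetine comparisons and no other alternative, with 200 genes changed 1.5-, 2- or 4-fold and a seeded list of 15 among 30 random ones. At 2-fold, edgeR recovered 19.4% of the changed genes in granule cells, 74.6% in mossy cells and 83.6% in hippocampus. The seeded list was called in each of the 7 comparisons and 0 of 30 random lists in any. Genes were drawn independently of each other, so this does not test lists whose members vary together between libraries. Labels were regrouped in 100 random splits for mossy cells and for hippocampus, all 35 splits for granule cells and 40 for each other comparison. Correlations between sources used 100 permutations of labels. The ratio of chi-square to degrees of freedom between replicate pairs was 7.31 to 448, so no library is a copy of another. No gene-set collection and no other study was used.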

Results

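RNA sequencing counts were available for 34 mouse libraries from wild-type hippocampus, after treatment with fluoxetine, a selective serotonin reuptake inhibitor, or with vehicle. The labels give 3 sources. Granule cells, the principal neurons of the dentate gyrus, had 4 vehicle and 4 fluoxetine libraries. Mossy cells, excitatory neurons of the dentate hilus, had 6 vehicle and 7 fluoxetine libraries, and hippocampus had 6 and 7. Translating ribosome affinity purification (TRAP), which pulls down tagged ribosomes with the mRNAs they carry, is given as the extraction for every library. The labels do not say which cells carried the tag in the hippocampus libraries, or whether those hold bound or input RNA. They give no dose and no duration. Total counts ranged from 14.1 to 40 M in granule cells, from 23.6 to 43.5 M in mossy cells and from 23.9 to 45 M in hippocampus. Between 14579 and 16462 genes had a count in a granule-cell library, 15232 to 16619 in a mossy-cell library and 17600 to 18210 in a hippocampus library. Rn45s, the ribosomal RNA precursor, took 2.77% ± 2.14 of counts in granule-cell vehicle libraries and 2.78% ± 3.32 with fluoxetine (SD, n = 4 and 4). Its share was 17% ± 2.21 and 20% ± 1.87 in mossy cells and 12.1% ± 0.468 and 12.8% ± 1.28 in hippocampus (n = 6 and 7). The replicates are not stated to be separate animals, so the p-values measure the spread between these samples and nothing wider. Levels are CPM, counts scaled to library size, as mean ± SD, and changes are log2 fold changes of fluoxetine against vehicle, with standard errors where marked SE.

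The comparison in mossy cells asked which ribosome-bound mRNAs of the libraries so labelled change with fluoxetine. With vehicle, interneuron markers were also higher in these libraries than in the hippocampus libraries, as given below. A change in them, such as that of a peptide gene, can therefore not be assigned to mossy cells alone. Camera called the lists of neuropeptides, peptide processing, ion channels, glutamate receptors and lysosomal proteins higher with fluoxetine, but none of these held with an estimated correlation, and in peptide processing alone did most of the members pass. Slc17a7, the vesicular glutamate transporter on chromosome 7 (GRCm38, 45163949 to 45176142), rose from 524 ± 51.3 to 1040 ± 211 CPM, a log2 change of 0.99 ± 0.12 (SE, adjusted p = 0.000256 in edgeR, n = 6 and 7). The peptide mRNA Cck rose from 639 ± 30.8 to 1120 ± 239 CPM (0.81 ± 0.12 SE, adjusted p = 0.00076). All 7 fluoxetine libraries lay above every vehicle library for both. The level of Penk, the enkephalin precursor, rose from 11 ± 1.61 to 23.8 ± 13 CPM (1.11 ± 0.27 SE, adjusted p = 0.0114), with 5 of 7 libraries above every vehicle library. Of 14229 genes tested, 1325 passed an adjusted p of 0.05 in edgeR, of which 1146 rose and 179 fell. The number that fell was 285 with upper quartile scaling, 320 with 1 surrogate variable, 396 with DESeq2 and 417 with limma-voom, and ran from 72 to 332 without 1 library.

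Among the 21 measured neuropeptides, 8 rose, none fell and 13 did not pass, with the same 8 adjusted over the list alone. They were Adcyap1, Cck, Gal, Nmb, Penk, Pnoc, Sst and Vgf. The list's median log2 change was 0.60 (camera adjusted p = 0.000194, and adjusted p = 0.151 with an estimated correlation). Gal, the galanin precursor, rose by 1.64 ± 0.42 (SE), but by 0.88 without fluoxetine library 2. Adcyap1, the PACAP precursor, rose by 0.58 (adjusted p = 0.0281) and Sst, somatostatin, by 0.60 (adjusted p = 0.0485). Neither Npy (0.67, adjusted p = 0.218) nor Pdyn (0.10, adjusted p = 0.948) passed. Bdnf, which encodes a neurotrophin, was close to the threshold (0.47, adjusted p = 0.0521). In the list of granins and peptide processing, 12 of 18 members rose and 2 fell (14 and 3 adjusted over the list alone), with a median of 0.50. Its camera adjusted p was 9.16e-08, and adjusted p = 0.0982 with an estimated correlation. Ptprn, a dense-core vesicle protein, rose by 0.83 (adjusted p = 0.000809), Pcsk2, a prohormone convertase, by 0.63 and Vgf by 0.80. Of 27 neuropeptide receptors 7 rose (13 adjusted over the list alone, median 0.51, camera adjusted p = 7.47e-05, adjusted p = 0.171 with an estimated correlation). Cckbr, a cholecystokinin receptor, rose by 0.97. Fluoxetine library 2 had the highest values of Gal, Npy and Bdnf in this group, at 58.9, 1370 and 39.1 CPM.

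Several lists of channels and receptors were called higher as well, none of them with an estimated correlation. Of 32 voltage-gated sodium and calcium channels 15 rose and 1 fell (20 and 1 adjusted over the list alone), and Cacna1i rose by 0.77. The median was 0.38 (camera adjusted p = 8.84e-11, adjusted p = 0.0695 with an estimated correlation). Potassium channels had 8 of 75 higher (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.52e-06, adjusted p = 0.151 with an estimated correlation). Of 15 ionotropic glutamate receptor genes 7 rose (11 adjusted over the list alone), among them Grin1, the obligatory NMDA receptor subunit, which went from 241 to 412 CPM. This list's median was 0.40 (camera adjusted p = 7.9e-08, adjusted p = 0.14 with an estimated correlation). Metabotropic glutamate receptors had 2 of 7 higher (5 adjusted over the list alone, camera adjusted p = 0.000266, adjusted p = 0.0795 with an estimated correlation). GABA-A receptors had 4 of 12 higher (7 adjusted over the list alone, camera adjusted p = 0.000263, adjusted p = 0.248 with an estimated correlation). In the synaptic vesicle list 5 of 20 rose (8 adjusted over the list alone), including Syp, which went from 1000 to 1620 CPM. This list alone kept its call with an estimated correlation (adjusted p = 0.0482, against 0.000243 with the preset one), at a median of 0.18 that became 0.02 with the correction for transcript GC content and length. Dopamine and adrenergic receptors had 2 of 9 higher (5 adjusted over the list alone, 0 with the GC content and length correction, camera adjusted p = 0.001, adjusted p = 0.0695 with an estimated correlation), while Drd2 itself reached 0.49 (adjusted p = 0.0789) and Drd1a 0.53 (adjusted p = 0.363). Mossy cell markers had 3 of 12 higher (5 adjusted over the list alone, camera adjusted p = 0.000366, adjusted p = 0.0982 with an estimated correlation), led by Ephb6 at 0.99, whereas Calb2 stood at 0.07 (adjusted p = 0.845). None of the 12 serotonin receptor and transporter genes passed (median 0.25, camera adjusted p = 0.18), with Htr5b at 0.39, Htr1a at 0.09 and Htr4 at 0.09. The 4 genes of the p11 complex did not pass either (median −0.05, camera adjusted p = 0.655), S100a10 being at 0.13.

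Organelle lists followed. Of 20 lysosomal genes 10 rose (12 and 1 adjusted over the list alone, median 0.50), including Psap, which encodes prosaposin, at 0.64 and the protease gene Ctsd at 0.65 (camera adjusted p = 7.9e-08, adjusted p = 0.0982 with an estimated correlation). Cholesterol synthesis had 6 of 17 higher (8 adjusted over the list alone, median 0.47), with Srebf2, which encodes a transcription factor of the pathway, at 0.64 (camera adjusted p = 5.94e-05, adjusted p = 0.248 with an estimated correlation). The list of endoplasmic reticulum stress and chaperones had 6 of 16 higher (11 adjusted over the list alone, median 0.47), with Pdia3 at 0.52 (camera adjusted p = 1.4e-06, adjusted p = 0.0982 with an estimated correlation). Growth factors and their receptors had 3 of 14 higher (5 adjusted over the list alone), among them Ntrk2 at 0.46 (camera adjusted p = 0.0138, adjusted p = 0.151 with an estimated correlation). Translation factors had a median of −0.11, with 2 of 65 higher and 1 lower, and nuclear-encoded oxidative phosphorylation genes −0.05, with 2 of 76 higher and 1 lower. Both lists had a camera adjusted p of 0.0138 (adjusted p = 0.151 and 0.593 with an estimated correlation). The oxidative phosphorylation median turned to 0.004 with the GC content and length correction, and its call ended without fluoxetine library 3 (adjusted p = 0.0643) or library 4. Adjusted over the list alone, translation factors had 2 higher and 1 lower and oxidative phosphorylation none. Heat shock genes (median −0.12, camera adjusted p = 0.053) had 2 of 12 lower, or 4 adjusted over the list alone. Dnaja1, an Hsp40 chaperone gene, fell by 0.36 (adjusted p = 0.0253). Cytosolic ribosomal proteins (median −0.05, camera adjusted p = 0.0525) had 1 of 79 lower. With 1 library left out in turn, camera called ribosomal proteins lower in 8 and heat shock genes lower in 5 of 13 fits.

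Markers of other cell types also moved in the mossy-cell libraries. Microglia markers had 4 of 8 higher (6 adjusted over the list alone, median 2.25), and Csf1r, the receptor of microglial survival factors, went from 1.63 ± 0.583 to 9.17 ± 12.1 CPM. Its change of 2.49 became 1.52 without fluoxetine library 4, which held 36.1 CPM. Astrocyte markers had 3 of 12 higher (6 adjusted over the list alone, median 0.70), with the glutamate transporter Slc1a3 at 1.80 (adjusted p = 0.0407), or 0.69 (adjusted p = 0.154) without library 4. Camera adjusted p was 0.000705 for microglia and 0.00274 for astrocytes, and adjusted p = 0.248 and 0.374 with an estimated correlation. Oligodendrocyte markers had 1 of 12 higher, also adjusted over the list alone (median 0.58, camera adjusted p = 0.0386, adjusted p = 0.5 with an estimated correlation). That call ended without vehicle library 4 or 5 or fluoxetine library 7, and without fluoxetine library 4 it reached an adjusted p of 0.14. Ttr, the choroid plexus gene for transthyretin, fell by 4.50 ± 1.16 (SE), from 73.8 ± 102 to 3.25 ± 2.66 CPM (adjusted p = 0.018), although no fluoxetine library lay below every vehicle library. It fell by 3.77 without vehicle library 2 (adjusted p = 0.0601) and was 3.25 higher without vehicle libraries 1, 2 and 4 (adjusted p = 0.167). The 3 measured choroid plexus markers had a median of −0.80 (camera adjusted p = 0.52), endothelial and mural markers 0.27 (0.427), CA1 and CA2 pyramidal markers 0.37 (0.276) and CA3 pyramidal markers 0.65 (0.1). In the CA3 list 3 of 9 rose, among them Nptx1 at 0.87, and 1 fell (6 and 2 adjusted over the list alone). Interneuron markers had 3 of 11 higher and 1 lower (4 and 2 adjusted over the list alone, median 0.18, camera adjusted p = 0.52), the lower one being Gad1, a GABA-synthesising enzyme, at −0.33. Granule cell markers had 1 of 12 lower, Stxbp6 at −0.38, a median of 0.05 and a mean of −0.05 (camera adjusted p = 0.314, downward). Calb1 stood at −0.22 (adjusted p = 0.224), Prox1 at −0.34 (0.127), Tdo2 at −0.67 (0.364) and Dsp at 0.06 (0.943). Immature granule cell markers, activity-regulated genes and glucocorticoid-responsive genes had none of 10, 22 and 14 passing, with medians of 0.06, 0.09 and 0.01 (camera adjusted p = 0.693, 0.427 and 0.937, the first and last downward). Pde1c, a calcium-regulated phosphodiesterase, fell by 0.60 (adjusted p = 0.0103).

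With 1 library left out in turn, 773 to 1744 genes passed in mossy cells. The count was 855, 837, 773 and 859 without vehicle library 2, 3, 4 and 6. Leaving out fluoxetine libraries 2 and 4 left 753 genes, vehicle libraries 1, 2 and 4 left 28, and vehicle libraries 3, 5 and 6 left 103, of which 718, 27 and 98 were among the 1325. In those fits granins had 9, 1 and 1 members higher, neuropeptides 4, 0 and 1, sodium and calcium channels 11, 1 and 1, lysosomal genes 7, 1 and 0 and microglia markers 2, 0 and 0. Without fluoxetine libraries 2 and 4 neuropeptide receptors had 1 of 26 higher and astrocyte markers 0. The list medians stayed positive, at 0.397, 0.451 and 0.533 for granins, 0.432, 0.647 and 0.561 for neuropeptides, 0.335, 0.44 and 0.34 for sodium and calcium channels, 0.423, 0.469 and 0.51 for lysosome and 1.52, 2.56 and 1.61 for microglia. Nmb lost its call without vehicle library 4 (adjusted p = 0.0733). Dnaja1 lost it without vehicle library 3 (0.0607), 4 (0.067) or 6 (0.0623). Adcyap1 did so without vehicle library 1 (0.0742), 2 (0.0645), 3 (0.0612) or 4 (0.0916) or fluoxetine library 2 (0.0586). Stxbp6 and Gad1 lost theirs in 7 of 13 such fits (adjusted p up to 0.0895 and 0.0988), Slc1a3 in 6 and Sst in 10 (up to 0.134). Bdnf passed without fluoxetine library 6 (0.035) or 7 (0.0392), Drd2 without fluoxetine library 3 (0.0279) and Prox1 without fluoxetine library 4 (0.0186).

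**Figure D1:**
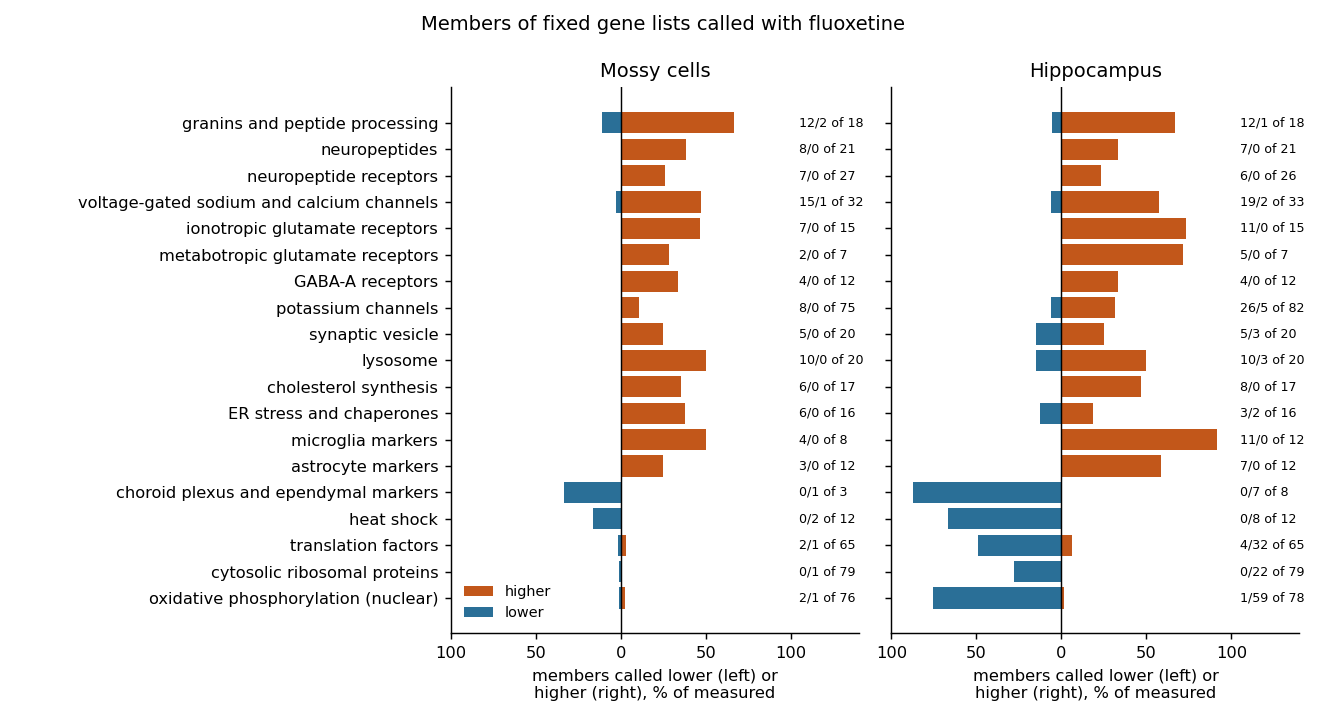
Percent of the measured members of 19 fixed gene lists that passed an adjusted p of 0.05 as higher (right) or lower (left) with fluoxetine, in mossy cells and in hippocampus, with the counts beside each bar. Granins and peptide processing had 12 of 18 members higher in both, and oxidative phosphorylation had 59 of 78 lower in hippocampus against 1 of 76 in mossy cells.

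The hippocampus comparison asked the same of the hippocampus-labelled RNA. Camera called lists of ion channels, glutamate receptors, peptide processing and microglia higher and those of oxidative phosphorylation, translation and heat shock lower, but 0 of the 20 lists called here held with an estimated correlation. Snhg11, a neuronal long noncoding RNA, rose from 395 ± 92.4 to 941 ± 246 CPM (1.25 ± 0.17 SE, adjusted p = 0.000343 in edgeR, n = 6 and 7), and Trank1 from 124 to 285 CPM (1.2 ± 0.18 SE). Hsp90aa1, a cytosolic chaperone, fell from 877 ± 20.8 to 679 ± 47.0 CPM (−0.37 ± 0.05 SE, adjusted p = 0.000424). Of 15596 genes tested, 4705 passed an adjusted p of 0.05 in edgeR, of which 2411 rose and 2294 fell. The higher share was 51.2%, and 35.1% of 4804 genes with the GC content and length correction.

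Among the lists called lower were those of the energy and protein synthesis machinery. Of 78 oxidative phosphorylation genes 59 fell and 1 rose (65 and 2 adjusted over the list alone, median −0.22). Atp5a1, a subunit of ATP synthase, fell from 776 to 608 CPM (−0.35) and Ndufa8, a complex I subunit, by 0.33. Camera gave this list an adjusted p of 9.93e-17, and adjusted p = 0.19 with an estimated correlation. Translation factors had 32 of 65 lower and 4 higher (32 and 5 adjusted over the list alone, median −0.17), with Eif4a2 at −0.38 (camera adjusted p = 6.16e-06, adjusted p = 0.167 with an estimated correlation). Cytosolic ribosomal proteins had 22 of 79 lower (21 adjusted over the list alone, median −0.13), with Rpl7 at −0.29 (camera adjusted p = 7.02e-07, adjusted p = 0.46 with an estimated correlation). Of 12 heat shock genes 8 fell, also adjusted over the list alone (median −0.28, camera adjusted p = 1.77e-05, adjusted p = 0.156 with an estimated correlation). Glucocorticoid-responsive genes had 4 of 14 lower (5 adjusted over the list alone, median −0.16), among them the glucocorticoid receptor gene Nr3c1 at −0.27. The call of that list (camera adjusted p = 0.0215, adjusted p = 0.418 with an estimated correlation) ended without fluoxetine library 2 (0.0502).

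Among neuronal lists, sodium and calcium channels had 19 of 33 higher and 2 lower (23 and 2 adjusted over the list alone), with Cacna1a, the P/Q-type calcium channel subunit, up from 61.6 to 92.6 CPM (0.59, adjusted p = 0.000169). The median was 0.34 (camera adjusted p = 7.23e-10, adjusted p = 0.173 with an estimated correlation). Potassium channels had 26 of 82 higher and 5 lower (28 and 5 adjusted over the list alone), with Kcnt1 at 0.76 (camera adjusted p = 2.9e-05, adjusted p = 0.231 with an estimated correlation). With the GC content and length correction the higher members of these lists numbered 14 and 14, and those of metabotropic glutamate receptors 2. Ionotropic glutamate receptors had 11 of 15 higher (12 adjusted over the list alone), with Grin1 at 0.45, metabotropic ones 5 of 7 (5 adjusted over the list alone) and GABA-A receptors 4 of 12 (6 adjusted over the list alone). Their camera adjusted p were 4.19e-07, 0.00219 and 0.00893, and adjusted p = 0.19, 0.173 and 0.46 with an estimated correlation. Granins and peptide processing had 12 of 18 higher and 1 lower (13 and 1 adjusted over the list alone, median 0.39), Ptprn rising from 184 to 267 CPM. That list's camera adjusted p was 4.73e-05, and adjusted p = 0.231 with an estimated correlation. Of 21 neuropeptides 7 rose, also adjusted over the list alone: Cck, Gal, Grp, Penk, Sst, Vgf and Vip (median 0.37, camera adjusted p = 0.0155, adjusted p = 0.417 with an estimated correlation). Penk went from 12.3 to 26.1 ± 22.7 CPM (1.08 ± 0.34 SE, adjusted p = 0.025), or 0.54 without fluoxetine library 2, which held 76.1 CPM, the highest, as it did for Npy, Vgf and Bdnf (109, 61.9 and 72.5 CPM). Cck rose by 0.28 and Vgf by 0.39 (0.22 without fluoxetine library 2, adjusted p = 0.0559). Neuropeptide receptors had 6 of 26 higher, also adjusted over the list alone (camera adjusted p = 7e-04, adjusted p = 0.205 with an estimated correlation). Dopamine and adrenergic receptors had 3 of 10 higher (5 adjusted over the list alone, camera adjusted p = 0.0077, adjusted p = 0.406 with an estimated correlation). Mossy cell markers had 3 of 12 higher, also adjusted over the list alone (median 0.28, camera adjusted p = 0.0215, adjusted p = 0.19 with an estimated correlation), with Ephb6 at 0.59. Slc17a7 rose by 0.55 (575 to 841 CPM), yet the synaptic vesicle list as a whole was not called, with 5 of 20 higher and 3 lower (5 and 4 adjusted over the list alone, median −0.01, mean 0.06, camera adjusted p = 0.547, upward). Cholesterol synthesis had 8 of 17 higher, also adjusted over the list alone, with Srebf2 at 0.45 (camera adjusted p = 0.0233, adjusted p = 0.587 with an estimated correlation), a call that ended without fluoxetine library 2 (0.211). Lysosomal genes had 10 of 20 higher and 3 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.0215, adjusted p = 0.587 with an estimated correlation).

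In hippocampus the microglia and astrocyte lists were called higher and the choroid plexus list lower, none of the 3 with an estimated correlation. Microglia markers had 11 of 12 higher, also adjusted over the list alone (median 1.35), Tmem119 rising from 2.71 to 8.99 CPM (1.72), Csf1r from 5.56 to 16.9 CPM (1.59) and Cx3cr1 by 1.39. Astrocyte markers had 7 of 12 higher, also adjusted over the list alone (median 0.70), with the water channel gene Aqp4 at 0.87 and the glutamate transporter Slc1a2 at 0.85 (1100 ± 88.1 to 1980 ± 1260 CPM). Camera gave an adjusted p of 6.16e-06 for microglia and 0.0134 for astrocytes, and adjusted p = 0.393 and 0.587 with an estimated correlation. Fluoxetine library 4 was the highest for Csf1r, Cx3cr1, Aqp4, Slc1a2 and Ntrk2, and without it their changes were 1.02, 0.99, 0.55, 0.46 and 0.35, against 0.58 for Ntrk2 with all libraries. Without fluoxetine libraries 2 and 4 the microglia list had 8 members higher (median 0.73) and the astrocyte list 6 (median 0.24). Choroid plexus and ependymal markers had 7 of 8 lower, also adjusted over the list alone (median −1.69, camera adjusted p = 0.00855, adjusted p = 0.475 with an estimated correlation). Ttr went from 1810 ± 2360 to 34.0 ± 34.3 CPM (−5.74) and Clic6, a choroid plexus chloride channel gene, from 30.5 ± 39.7 to 1.08 CPM (−4.80), but only 1 of 7 fluoxetine libraries had less Ttr than every vehicle library. Without vehicle libraries 1, 2 and 4 none of the 8 passed (median 0.44), and Ttr and Clic6 were 2.21 and 1.83 higher (adjusted p = 0.121 and 0.0738). Among lists not called, granule cell markers had 2 of 12 higher and 4 lower (2 and 5 adjusted over the list alone, median −0.21, camera adjusted p = 0.185): C1ql2 rose by 0.58, and Prox1 and Calb1 fell by 0.24 and 0.46. Interneuron markers had 4 of 11 higher and 3 lower (5 and 3 adjusted over the list alone, median 0.03, camera adjusted p = 0.704), with Sst at 0.34 and Pvalb and Gad2 at −0.33 and −0.28. Oligodendrocyte markers had 3 of 12 lower (2 adjusted over the list alone), among them Cnp at −0.29 (median 0.08, camera adjusted p = 0.988). The CA1 and CA2 list had a median of 0.17 (2 of 11 higher and 1 lower, or 3 and 2 adjusted over the list alone, camera adjusted p = 0.437), the CA3 list 0.07 (3 of 9 higher, 3 lower, 0.95) and endothelial and mural markers 0.09 (1 of 12 lower, 0.94). Serotonin receptors and transporter had 3 of 13 higher (2 adjusted over the list alone, median 0.13, camera adjusted p = 0.242), with Htr4 at 0.41, Htr5b at 0.38 (adjusted p = 0.0909) and Htr1a at 0.002 (adjusted p = 0.992). Activity-regulated genes had 1 of 22 higher and 2 lower (median −0.05, mean 0.09, camera adjusted p = 0.75), immature granule cell markers 1 of 12 higher and 2 lower (median 0.12, camera adjusted p = 0.865, downward) and growth factors 4 of 15 higher and 1 lower (median 0.12, 0.173). The endoplasmic reticulum list had 3 of 16 higher and 2 lower (median 0.15, 0.0808), a list called without vehicle library 1, fluoxetine library 1 or fluoxetine library 6. The p11 list had no member passing (median −0.12, 0.637), with S100a10 at −0.09. Not passing either were Drd1a (0.81, adjusted p = 0.0512), Nmb (0.44, 0.0739), Tdo2 (−0.77, 0.0781), Bdnf (0.27, 0.122), Drd2 (0.28, 0.197), Npy (0.39, 0.257), Dsp (−0.23, 0.371), Adcyap1 (0.23, 0.472), Calb2 (0.12, 0.475) and Pdyn (−0.22, 0.574).

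Leaving out each library in turn gave 3447 to 5046 genes in hippocampus, and leaving out vehicle libraries 1, 2 and 4 gave 1031, of which 981 were among the 4705. Without those 3 libraries 13 oxidative phosphorylation genes fell, and 30 without the other 3 vehicle libraries. The same fits left 3 and 6 microglia markers, 0 and 0 astrocyte markers, 4 and 8 granins and 0 and 5 neuropeptides higher. The medians stayed on their side, at 1.455 and 1.275 for microglia, 0.788 and 0.634 for astrocytes, 0.319 and 0.446 for granins, 0.299 and 0.418 for neuropeptides and −0.187 and −0.234 for oxidative phosphorylation. Penk lost its call without vehicle library 5 (adjusted p = 0.0502), and Cck, Htr4 and Vgf lost theirs in 7, 8 and 8 of 13 fits without 1 library (up to 0.103, 0.103 and 0.0942). Drd1a passed in 5 such fits (down to 0.0192), Nmb without vehicle library 6 (0.0253) and Tdo2 without fluoxetine library 1 (0.0366) or 2 (0.0274).

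**Figure D2:**
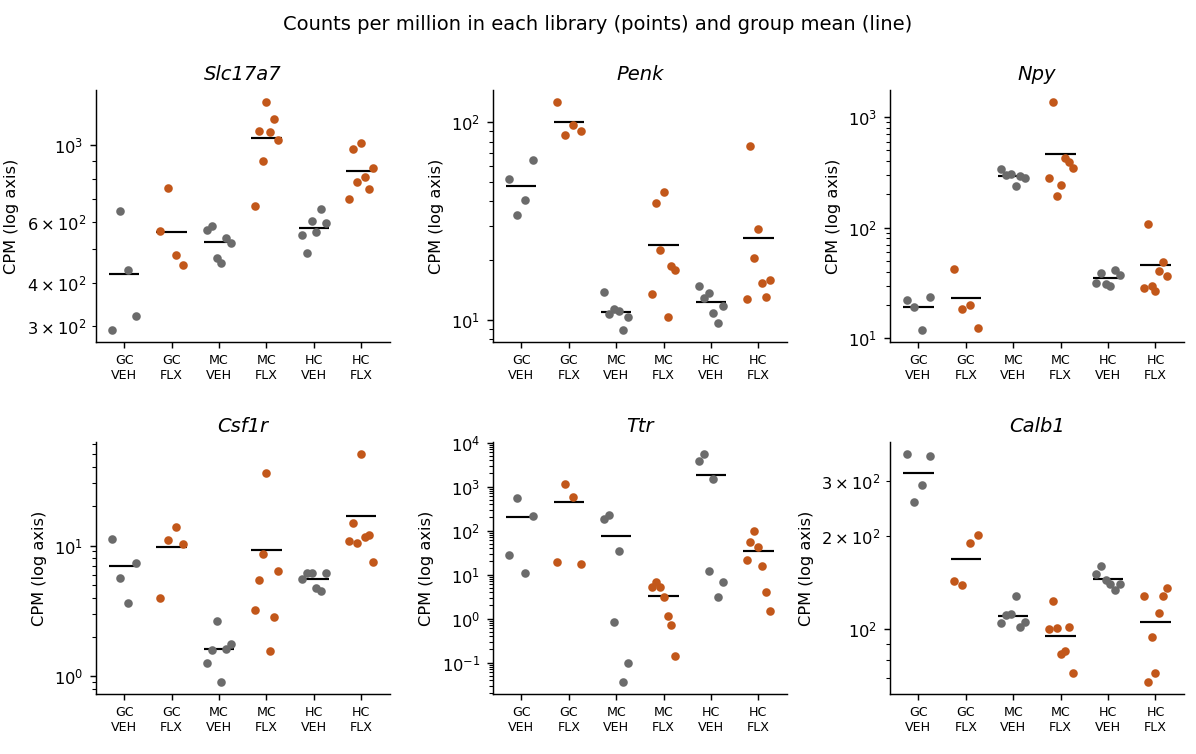
Level of 6 genes in each library (points, CPM on a log axis) in the 6 groups, with a line at the group mean (GC granule cells, MC mossy cells, HC hippocampus, VEH vehicle, FLX fluoxetine). Slc17a7 averaged 524 and 1040 CPM in mossy cells with vehicle and fluoxetine, while Ttr in hippocampus vehicle libraries had a mean of 1810 and an SD of 2360 CPM.

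Whether the fluoxetine effect differed between mossy cells and hippocampus was tested as an interaction. The difference passed for 7 of 15922 genes in edgeR, 1 with a higher and 6 with a lower effect in mossy cells (1790 genes at an unadjusted p under 0.05, against 796 by chance). Nvl, a nucleolar ATPase gene, had a log2 difference of −0.83 ± 0.13 (SE, adjusted p = 0.00714) and Srek1, a splicing regulator gene, −0.80 ± 0.13 (SE, adjusted p = 0.00714), and both passed in 26 of 26 fits without 1 library. Ly6e was 0.62 ± 0.12 (SE, adjusted p = 0.0464), a call kept in 8 of 26, and D4Wsu53e −0.78 (adjusted p = 0.0264), kept in 17. The effect on Cck, 0.55 larger in mossy cells, did not pass (adjusted p = 0.2). Oxidative phosphorylation (median difference 0.18, camera adjusted p = 6.44e-10), the endoplasmic reticulum list (0.32, 0.000465), ribosomal proteins (0.11, 0.000681), synaptic vesicle (0.18, 0.000681), oligodendrocyte markers (0.64, 0.0147), CA3 pyramidal markers (0.33, 0.0226), heat shock (0.21, 0.0244), lysosome (0.20, 0.0373), glucocorticoid-responsive genes (0.17, 0.0407) and cholesterol synthesis (0.22, 0.0409) had the more positive effect in mossy cells. The median difference over all genes was itself 0.065, and the 0.11 of ribosomal proteins became 0.054 with upper quartile scaling. Not 1 of these 10 lists held with an estimated correlation (adjusted p = 0.116 for synaptic vesicle, 0.417 for oxidative phosphorylation and the endoplasmic reticulum list, 0.826 for ribosomal proteins). The voltage-gated sodium and calcium channels (median difference 0.15, mean −0.02, camera adjusted p = 0.491), the dopamine and adrenergic receptors (0.03, −0.15, 0.878) and the p11 complex (0.10, camera downward, 0.898) had signs that disagreed and no call. The count of 7 rose to 116 with replicate number as a block, and ran from 2 without hippocampus vehicle library 1, 2, 3 or 5 or fluoxetine library 1, 3, 5 or 6 to 41 without mossy-cell fluoxetine library 1. It was also 12, 3, 25 and 30 without hippocampus vehicle 4, vehicle 6, fluoxetine 4 and fluoxetine 7, and 20, 3, 3, 4, 4, 15 and 19 without mossy-cell vehicle 2, 3, 4, 5, 6, fluoxetine 3 and fluoxetine 4.

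Across 14082 genes tested in both, the fluoxetine changes in mossy cells and hippocampus had a Pearson r of 0.448 and a Spearman rho of 0.473. Genes are not independent replicates: 100 permutations of the labels, kept in step between the sources by replicate number, gave a mean r of 0.212 (permutation p = 0.0198, two-sided). For granule and mossy cells r was 0.142 (permutation p = 0.0297, rho 0.126) and for granule cells and hippocampus 0.097 (permutation p = 0.099, rho 0.118). Adjusted over these 3 relations, the permutation p were 0.0446, 0.0446 and 0.099. Among genes with a mean CPM of at least 5 in both sources r was 0.683, 0.173 and 0.153 (0.388 as the mean of permutations for mossy cells and hippocampus), and the adjusted permutation p of 0.0594, 0.0594 and 0.1782 passed in none. Of the genes called in both, 828 rose in mossy cells and in hippocampus, 112 fell in both and 3 were called in opposite directions. Independent comparisons would share 179.5 and 28.7, which is too low a mark here, as permuted labels gave a mean r of 0.212, and no permuted overlap was run.

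In granule cells no gene passed an adjusted p of 0.05 in edgeR (14236 tested, smallest adjusted p 0.323, 1056 at an unadjusted p under 0.05 against 712 by chance, n = 4 and 4). Limma-voom called none and DESeq2 77 genes (54 higher, 23 lower), but 32 of its 109 simulated calls were false (edgeR 3 of 56). Values below are therefore descriptive for single genes. Calb1, the calbindin gene that marks mature granule cells, was 318 ± 53.3 CPM with vehicle and 168 ± 31.5 with fluoxetine (−0.92 ± 0.20 SE, adjusted p = 0.323). Prox1, the granule-cell identity factor, was 349 and 222 CPM (−0.65, adjusted p = 0.408), and Tdo2, tryptophan dioxygenase, 17.7 and 7.14 CPM (−1.31, adjusted p = 0.407). Higher values came from App (446 ± 119 and 1060 ± 185 CPM, 1.25), its relative Aplp2 (318 and 688 CPM, 1.11), Reln (1.28), Col6a1 (2.68), Sept6 (0.99) and Penk (47.6 ± 13.4 and 99.9 ± 18.2 CPM, 1.07), each with an adjusted p of 0.323.

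As sets, camera called 14 of 33 lists in granule cells and none with an estimated correlation. As no gene passed over all genes, rose and fell give camera's direction. Granule cell markers fell (median −0.39, camera adjusted p = 0.000124, adjusted p = 0.0548 with an estimated correlation), with 4 of 12 lower adjusted over the list alone: Calb1, Il1r1, Prox1 and Tdo2. Astrocyte (0.53), oligodendrocyte (0.63), microglia (0.85) and interneuron (0.45) markers rose, with 3, 4, 1 and 3 members higher adjusted over the list alone. Their camera adjusted p were 5.03e-05, 8.85e-05, 0.00121 and 0.00324, and adjusted p = 0.0548, 0.0548, 0.0548 and 0.0636 with an estimated correlation. Gfap, the astrocyte filament gene, was 1.34 (adjusted p = 0.323). Lysosomal genes rose (median 0.50, camera adjusted p = 9.32e-06, adjusted p = 0.0548 with an estimated correlation) with 4 higher adjusted over the list alone, Ctsb, Lamp1, Npc1 and Psap, the last at 512 and 897 CPM. Granins and peptide processing rose (0.31, camera adjusted p = 9.32e-06, adjusted p = 0.0548 with an estimated correlation), with Ptprn higher adjusted over the list alone. Synaptic vesicle (0.33, 0.00121), metabotropic glutamate receptors (0.33, 0.00613), cholesterol synthesis (0.26, 0.00613), CA3 pyramidal markers (0.42, 0.0189) and GABA-A receptors (0.43, 0.0297) rose, with adjusted p = 0.078, 0.235, 0.222, 0.211 and 0.225 with an estimated correlation. Adjusted over the list alone, Grm7 and Elavl2 were the 1 member higher in the metabotropic and CA3 lists. Ribosomal proteins (−0.38, camera adjusted p = 9.87e-16) and oxidative phosphorylation (−0.29, 2.05e-07) fell (adjusted p = 0.332 and 0.367 with an estimated correlation). The CA3 and GABA-A calls ended without vehicle library 3 or fluoxetine library 4 (highest adjusted p = 0.144 and 0.268, both without vehicle library 3).

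The other granule-cell lists were not called. Neuropeptides had a median of 0.12 and a mean of −0.03 (camera adjusted p = 0.837), with Penk higher and Cartpt (−2.42, adjusted p = 0.362 over all genes) lower adjusted over the list alone. Cck stood at −0.89, Vgf at 0.62, Npy at 0.27, Nmb at 0.18, Adcyap1 at −0.07 and Pdyn at 0.06. Serotonin receptors and transporter had a median of −0.10 (0.837), with Htr1a at 0.07, Htr4 at −0.10 and Htr5b at −0.25. Dopamine and adrenergic receptors had 0.31 (0.585), with Drd1a at 1.12 (adjusted p = 0.457) and Drd2 at 1.36 ± 1.12 (SE), a value that became −1.24 without fluoxetine library 4. The p11 complex had 0.20 (0.48), S100a10 being at 0.28, and neuropeptide receptors 0.24 (0.397). Activity-regulated genes had −0.34 (0.0582), a list called without vehicle library 1, fluoxetine library 3 or fluoxetine library 4, with Bdnf at 0.41. Sox11 (immature granule cells), Nov (CA1 and CA2) and Cacna2d3 (sodium and calcium channels) were higher and Ntf3 (growth factors) lower adjusted over the list alone. Growth factors had 0.30 (0.232), glucocorticoid-responsive genes −0.18 (0.201), ionotropic glutamate receptors 0.22 (0.226), potassium channels 0.05 with a mean of −0.05 (0.703) and sodium and calcium channels 0.01 (0.396). Translation factors had −0.10 (0.159), the endoplasmic reticulum list 0.10 with a mean of −0.03 (0.952) and heat shock 0.42 (0.0582), a list called without vehicle library 4 or fluoxetine library 2. Mossy cell markers had 0.18 (0.606, Calb2 at 0.42), immature granule cell markers 0.12 (0.244) and CA1 and CA2 markers 0.29 (0.0841, called without vehicle library 4). Endothelial and mural markers had −0.70 (0.966, called upward without vehicle library 3) and choroid plexus markers 0.83 (0.172, called without vehicle library 2, fluoxetine library 1 or fluoxetine library 4). With a term for replicates 1 and 4 against 2 and 3 these 2 medians were 0.038 and −0.08, and that of serotonin receptors 0.016. Dsp, a granule marker, was at −0.42 (adjusted p = 0.796). Il1r1, Cartpt, Gfap and Psap were singled out after their values were seen. In simulation edgeR recovered 1.49%, 19.4% and 59.1% of genes changed 1.5-, 2- and 4-fold, against 38.8%, 74.6% and 95.5% in mossy cells.

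**Figure D3:**
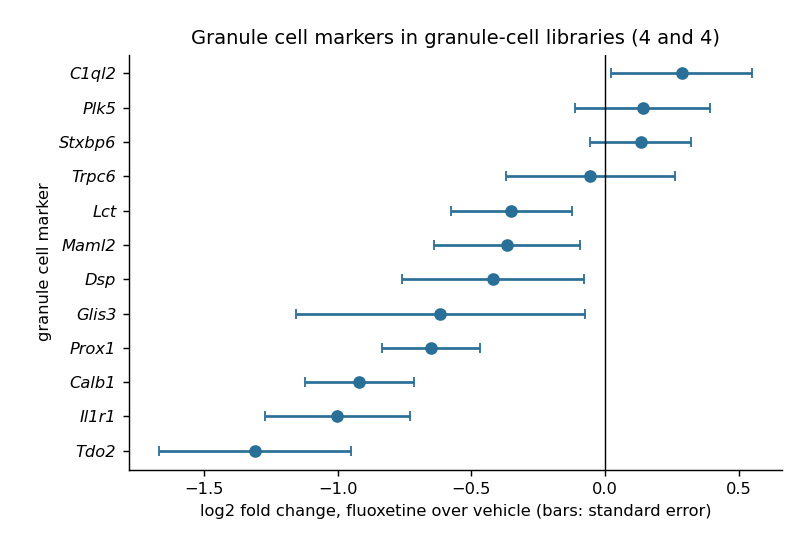
Log2 fold change of fluoxetine against vehicle (points, bars are standard errors) for the 12 granule cell markers in granule-cell libraries (n = 4 and 4). Tdo2 was lowest at −1.31, Calb1 was −0.92 and Prox1 −0.65, and no gene passed the adjusted threshold in edgeR.

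The difference in fluoxetine effect between granule and mossy cells passed for 28 of 15444 genes in edgeR, 8 with the higher and 20 with the lower effect in granule cells. Cck had a difference of −1.68, Cartpt −2.77, the glial-derived factor receptor gene Gfra2 −1.82, the postsynaptic scaffold gene Shank2 −1.35, Kitl −1.66 and Trp53i11 −1.32. Sept6 (1.19, adjusted p = 0.0201), Elavl2 (1.14), Cadps (0.93), Kif3a (0.98) and Wdr46 (1.73) were on the other side, and the adjusted p of the 11 ran from 0.0201 to 0.0449. Calb1 (−0.69, adjusted p = 0.132) and Penk (−0.03, adjusted p = 0.983) did not pass. Lists with a higher effect in granule cells were interneuron markers (0.44, camera adjusted p = 0.0462), choroid plexus markers (1.97, 0.0437) and heat shock (0.51, 0.0174). Lower effects came from ribosomal proteins (−0.32, 5.64e-11), oxidative phosphorylation (−0.28, 0.00246), the endoplasmic reticulum list (−0.33, 0.0106), potassium channels (−0.22, 0.0167), sodium and calcium channels (−0.38, 0.023) and neuropeptides (−0.42, 0.0437). None of the 9 held with an estimated correlation (adjusted p = 0.531 to 0.629). Both pyramidal lists, oligodendrocyte markers, granins, metabotropic glutamate receptors, GABA-A receptors and lysosome had a median, mean and camera direction of unlike sign, with no call. Every named call ended without at least 1 library, and the count was 0 without granule-cell fluoxetine library 3, mossy-cell vehicle library 3, 5 or 6 or mossy-cell fluoxetine library 5, and 354 without granule-cell fluoxetine library 2. It was 5, 61, 194, 2, 3 and 8 without granule-cell vehicle 1 to 4 and fluoxetine 1 and 4, and 8, 1, 3, 2, 15, 12, 1 and 18 without mossy-cell vehicle 1, 2 and 4 and fluoxetine 2, 3, 4, 6 and 7. With replicate number as a block edgeR called 0 genes (1150 at an unadjusted p under 0.05). Without a block DESeq2 called 276 and limma-voom 1.

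Mossy-cell and hippocampus vehicle libraries were compared to show what the mossy-cell RNA holds. Each source had a count table of its own, so source and table cannot be told apart here or between granule and mossy cells. Mossy cell and interneuron markers were higher in it and granule cell and glial markers lower, though of the glial lists oligodendrocyte markers alone held with an estimated correlation. Calb2, calretinin, was 14 CPM in hippocampus and 319 in mossy cells (4.51), Drd2 4.25 and 34.3 CPM (3.01), Sst 64.4 and 1520 CPM (4.56), Npy 31.8 and 324 CPM (3.35) and Prox1 189 and 30.1 CPM (−2.65). Of 15922 genes 10197 passed in edgeR, 4981 higher and 5216 lower in mossy cells. The higher share was 48.8%, and 64.8% with the GC content and length correction. The median over all genes was −0.04, and became −0.16 with upper quartile scaling, −0.12 without a filter and 0.21 with that correction, so changes are relative to it.

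Mossy cell markers had 9 of 12 higher and 2 lower (median 1.15, camera adjusted p = 0.000368, adjusted p = 0.0401 with an estimated correlation), with Nmb at 3.25. Glp1r and Ebf3, which are not on that list, were at 4.08 and 4.41. Interneuron markers had 10 of 11 higher and 1 lower (2.04, camera adjusted p = 1.11e-17, adjusted p = 0.000439 with an estimated correlation), among them Reln at 3.74 and the GABA vesicle transporter gene Slc32a1 at 2.90. Neuropeptides had 16 of 21 higher and 2 lower (1.62, camera adjusted p = 1.58e-05, adjusted p = 0.0568 with an estimated correlation), with Adcyap1 at 2.69, Vgf at 1.59 and Cck at 0.96, while Penk was 0.13 (adjusted p = 0.768). Granins had 15 of 18 higher (0.93, camera adjusted p = 2.03e-07, adjusted p = 0.0568 with an estimated correlation). Oxidative phosphorylation had 74 of 79 higher (0.90, camera adjusted p = 2.28e-28, adjusted p = 0.0326 with an estimated correlation), with Ndufb7 at 1.77 and Sdhb at 1.15. Synaptic vesicle had 13 higher (0.43, camera adjusted p = 0.000904, adjusted p = 0.0405 with an estimated correlation). Heat shock had 8 higher (0.34, 0.0181) and lysosome 12 (0.66, 0.0221), with adjusted p = 0.219 and 0.613 with an estimated correlation. Lower lists were granule cell markers (10 of 12 lower, −1.44, camera adjusted p = 5.1e-05, adjusted p = 0.0424 with an estimated correlation), oligodendrocyte markers (12 of 12, −3.57, 1.99e-15, 0.0326), astrocyte markers (12 of 12, −2.56, 6.13e-05, 0.324), microglia markers (12 of 12, −3.69, 0.00148, 0.467), endothelial and mural markers (11 of 12, −3, 0.00137, 0.184) and glucocorticoid-responsive genes (10 of 14, −0.67, 0.000422, 0.0568), each with the preset and then the estimated correlation. Examples were the myelin gene Mbp at −2.61, Aqp4 at −3.80, the microglial adaptor Tyrobp at −5.81, Vtn at −3.31, Mt2 at −2.62 and Maml2 at −1.84. Choroid plexus markers had 11 lower without a list call (−3.30, 0.0834). The nuclear noncoding RNAs Malat1 (−6.82, 11800 and 104 CPM, adjusted p = 1.44e-20) and Neat1 (−5.60) were lower too. Of the receptor genes, Htr3a was 2.79, Htr1a −0.77 and Htr4 −1.34, and S100a10 was 1.04 and Tdo2 −1.91. Calb1 was −0.10 (adjusted p = 0.52), and 0.50 with the GC content and length correction. Immature granule cell and CA3 markers, activity-regulated genes and ionotropic glutamate receptors had a median, mean and camera direction of unlike sign, with no call. Dsp, at −0.73 (adjusted p = 0.038), lost its call in 7 of 26 fits without 1 library (up to 0.0971).

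Granule and mossy cells with vehicle were compared to show what separates the purified RNAs. Prox1 was 29.4 CPM in mossy and 306 in granule cells (3.38), Calb2 311 and 13.5 CPM (−4.53), Npy 317 and 16.8 CPM (−4.24) and Kalrn, a synaptic exchange factor gene, 881 and 16900 CPM (4.26). Of 15444 genes 7123 passed in edgeR, 3671 higher and 3452 lower in granule cells. All 12 granule cell markers were higher (median 2.85, camera adjusted p = 9.34e-17, adjusted p = 3.5e-05 with an estimated correlation), among them Calb1 at 1.21, Tdo2 at 3.26, Dsp at 2.64 and Stxbp6 at 2.31. Plekha2, which is not on that list, was at 4.46. Mossy cell markers had 7 lower and 2 higher (−2.13, camera adjusted p = 0.000384, adjusted p = 0.015 with an estimated correlation), with Nmb at −5.64 and Drd2 at −4.93. Ebf3, also outside the list, was at −5.18. Interneuron markers had 10 lower and 1 higher (−2.48, camera adjusted p = 2.02e-12, adjusted p = 0.000366 with an estimated correlation), with Lhx6 at −3.01 and Sst at −3.26. Neuropeptides had 12 lower and 3 higher (−1.50, camera adjusted p = 0.00116, adjusted p = 0.117 with an estimated correlation): Adcyap1 was −3.10, Cck −1.50 and Vgf −1.63, but Penk 1.80. Granins had 11 lower (−0.76, 1.41e-05), oxidative phosphorylation 49 lower and 2 higher (−0.71, 6.57e-13) with Atp5d at −2.43, and synaptic vesicle 13 lower and 4 higher (−0.76, 0.000521) with Cplx1 at −1.64. With an estimated correlation these had adjusted p = 0.0957, 0.155 and 0.0288. Glucocorticoid-responsive genes had 8 higher (0.68, camera adjusted p = 0.000521, adjusted p = 0.0288 with an estimated correlation), with Klf9 at 2.08. Astrocyte (9 higher, 2.03), oligodendrocyte (11, 3.01), microglia (9, 3.26) and endothelial (10, 3.20) markers were higher in granule-cell libraries, with camera adjusted p of 0.00016, 1.58e-11, 0.00423 and 0.0238. Of those, oligodendrocyte markers held with an estimated correlation (adjusted p = 0.015, against 0.333, 0.417 and 0.644 for the others). Mbp was 2.25, Aqp4 2.93 and P2ry12 4.25. Immature granule cell markers, ionotropic glutamate receptors, potassium channels, translation factors and the endoplasmic reticulum list differed in sign between median, mean and camera, with no call. Htr4 was 2.60, Htr1a 0.83, Bdnf 1.46, Npy1r 1.62 and S100a10 −1.71.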

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

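Every test in this part was chosen after the result it bears on was seen, apart from the interactions and the plan to regroup the labels. The chi-square and Fisher's exact p treat genes as independent, which they are not.

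In 368 groups of libraries the highest or lowest library was compared with the rest of its group by Dixon's ratio, and 36 (9.78%) stood apart, where 5% would by chance. Fluoxetine libraries 2 and 4 of hippocampus held 5 each, granule-cell fluoxetine library 2 held 4, and fluoxetine libraries 2 and 4 of mossy cells 3 each. Hippocampus fluoxetine library 2 was highest for Bdnf (72.5 CPM), Gad2 (298), Npy (109), Penk (76.1) and Vgf (61.9). Fluoxetine library 4 there was highest for Aqp4 (122), Csf1r (50.3), Cx3cr1 (23.1), Ntrk2 (460) and Slc1a2 (4810). Library 3 was highest for Clic6 (2.67), and library 7 for Adcyap1 (4.72) and Cck (638). Among hippocampus vehicle libraries, number 1 was highest for Ntrk2 (177) and number 3 lowest for Ndufa8 (68.4). In mossy cells, fluoxetine library 2 was highest for Bdnf (39.1), Gal (58.9) and Npy (1370), library 4 for Csf1r (36.1), Psap (981) and Slc1a3 (64.5), library 1 for Pde1c (10.8) and Pdyn (2.54), library 6 for Cartpt (14.8) and library 7 for Tdo2 (2.24). Mossy-cell vehicle library 2 was highest for Klf9 (72.9), library 4 lowest for Glp1r (11) and library 5 lowest in total counts (26.1 M). Granule-cell fluoxetine library 2 had the highest Rn45s share (7.71%) and Nmb (1.61) and the lowest Cadps (244) and Elavl2 (70.6). Library 4 there was lowest for Adcyap1 (0.927) and highest for Drd2 (11.4). Granule-cell vehicle library 1 was lowest for Bdnf (48.3) and library 3 highest for Kalrn (23500).

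The effect of fluoxetine differed between mossy cells and hippocampus by the interaction test for Nvl (−0.83), Srek1 (−0.80), D4Wsu53e (−0.78), Uvssa (−1.19), A130077B15Rik (−0.79) and Ly6e (0.62), the first pair in each of 26 fits without 1 library. Uvssa (adjusted p = 0.0351) and A130077B15Rik (adjusted p = 0.045) were chosen after their values were seen and passed in 14 and 10 of those fits. Between granule and mossy cells edgeR called a difference for Sept6 (1.19), Cck (−1.68), Elavl2 (1.14), Shank2 (−1.35), Trp53i11 (−1.32), Cartpt (−2.77), Cadps (0.93), Gfra2 (−1.82), Kitl (−1.66), Kif3a (0.98) and Wdr46 (1.73). Each of these 11 calls ended without at least 1 library, the block called 0 genes and limma-voom 1, and regrouped labels gave up to 51 genes against 28, so chance cannot be excluded for them.

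Labels were regrouped for each count. Chance can be excluded for mossy cells (1 of 100 splits, the real one with 1325 genes against a highest other of 101) and hippocampus (1 of 100, 4705 against 1623). It can be excluded for mossy cells against hippocampus (1 of 40, 10197 against 4949), for their difference in fluoxetine effect (1 of 40, 7 against 1) and for granule against mossy cells (1 of 40, 7123 against 2002). It cannot be excluded for the difference in effect between granule and mossy cells (2 of 40, 28 against 51). For fluoxetine in granule cells the real split called 0 genes in edgeR and all 35 gave as many (1056 at an unadjusted p under 0.05, DESeq2 77, limma-voom 0). The highest other was 113, for replicates 1 and 4 against 2 and 3 of both treatments, which follows the Rn45s share and points to a structure of these samples. With a term for that split edgeR called 0 genes (smallest adjusted p 0.0502, 1541 at an unadjusted p under 0.05).

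In granule-cell libraries the granule cell markers were lower with fluoxetine (mean −0.45), while the astrocyte, oligodendrocyte, microglia, interneuron and CA3 lists were called higher, and each of these calls ended with an estimated correlation. The 12 markers differed beyond edgeR standard errors (−1.31 to 0.29, chi-square p = 2.98e-05). Other cells may express them unequally, so this cannot test a smaller granule-cell share. Chance cannot be excluded: the list alone was largest in 1 of 35 splits (exact permutation p = 0.0286), but it was picked from 33 lists, and 8 of 35 splits had some list as large (exact permutation p = 0.229). A term for the Rn45s split (camera adjusted p = 0.000119) decides nothing, as it is balanced over treatments, and a wider set of genes enriched in granule cells had been looked at before the heterogeneity test was chosen. A lower level of some granule-cell mRNAs with fluoxetine may stay open beside chance and a smaller share of granule-cell RNA, for a call that fails with an estimated correlation (adjusted p = 0.0548).

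In hippocampus, 10 noncoding RNAs that are depleted from mossy-cell libraries changed by a median of 0.71 with fluoxetine, and 7 rose: Malat1 (0.63), Meg3 (1.16), Miat (0.98), Ftx (0.87), Gdap10 (0.66), 6720401G13Rik (0.76) and A930011O12Rik (0.83), but not 2900052N01Rik (0.51, adjusted p = 0.111), Neat1 (−0.17, 0.655) or D7Ertd715e (−0.07, 0.645). The 10 spread beyond edgeR standard errors (chi-square p = 5.57e-14), but nuclear fractions may differ, so this cannot test a larger nuclear share. GC content and length left a median of 0.657 of 0.714. An exact permutation p of 0.00175 over 1716 splits (mean 0.63) cannot exclude chance, as the set was chosen after its rise was seen and first looked at with a looser bound on depletion. The labels do not say whether the hippocampus RNA was ribosome-bound, and chance, a change in the share of nuclear RNA, or one in expression of these RNAs with fluoxetine may stay open.

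Fluoxetine libraries numbered 2 stood highest for peptide and activity-regulated genes in both hippocampus and mossy cells. Of 37 list members, 12 were highest in library 2 of hippocampus, 14 in that of mossy cells and 9 in both (Npy, Tac2, Pnoc, Vgf, Fosb, Egr3, Nptx2, Bdnf and Inhba). A fault in 1 library preparation as the whole cause is argued against by the 33 members that had not stood apart, of which 6 were highest in both where the counts in each (8 and 11) give 2.67 by chance (one-sided Fisher's exact test p = 0.00822), a test that replaced one on all 37, which included the genes that prompted it. A vehicle sample under a wrong label is argued against by positions of 1.01 in hippocampus and 0.895 in mossy cells, where 0 is the vehicle and 1 the fluoxetine mean of the other libraries. No biological explanation was tested, since the design names none for 1 replicate, and a cause shared by the sample, such as tissue from 1 animal, stays open.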

How the results depend on the processing

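Alternatives chosen after seeing the data are listed with the processing. Scaling by DESeq2 size factors or upper quartile turned 0 of the lists called in any comparison, and the GC content and length correction turned 1, oxidative phosphorylation in mossy cells (0.004), in the 3 fluoxetine comparisons and mossy cells against hippocampus, the only ones it was run for. Total counts stayed within 1.5 times under the alternatives not named here. Counts by direction moved further where the total did not: genes lower in mossy cells numbered 285 with upper quartile scaling, 396 with DESeq2, 417 with limma-voom, 320 with 1 surrogate variable and 332, 111 and 273 without fluoxetine library 1, 5 and 7, against 179 (72 to 332 over all fits without 1 library), those lower in hippocampus 1362 without vehicle libraries 3, 5 and 6, against 2294, and those with the higher effect in granule than in mossy cells 4 with no filter and 4 without mossy-cell fluoxetine library 1, against 8. Ly6e kept its call in 8 of 26 fits without 1 library. Among list members called, the following moved by over 1.5 times and more than 1 member (main count in brackets). With the GC content and length correction, in mossy cells 5 potassium channels (8), 5 growth factors (3), 0 dopamine and adrenergic receptors (2) and 0 translation factors (2) were higher. In hippocampus 2 metabotropic receptors (5), 14 potassium channels (26), 1 translation factor (4), 1 CA3 marker (3) and 2 synaptic vesicle genes (5) were higher, and 7 synaptic vesicle genes (3), 14 ribosomal proteins (22), 3 granins (1), 3 CA1 and CA2 markers (1) and 5 activity-regulated genes (2) lower. Without fluoxetine libraries 2 and 4, in mossy cells 4 neuropeptides (8), 1 neuropeptide receptor (7), 2 microglia (4), 0 astrocyte (3), 0 CA3 (3) and 1 interneuron marker (3), 1 growth factor (3), 4 ionotropic receptors (7), 3 endoplasmic reticulum (6) and 3 synaptic vesicle genes (5) were higher. In hippocampus 4 neuropeptides (7), 4 cholesterol genes (8), 17 potassium channels (26) and 1 dopamine and adrenergic receptor, 1 serotonin receptor and 1 endoplasmic reticulum gene (3 each) were higher, and 3 cholesterol genes (0), 3 potassium channels (5) and 0 sodium and calcium channels (2) lower. Some medians of lists without a call turned as well. The agreement between sources passed in none of the 3 relations at a mean CPM of at least 5. Fluoxetine in granule cells gave 77 genes with DESeq2 and 0 with the block. In mossy cells 2023 genes passed at an adjusted p of 0.1, 2656 with the spread shared over 26 libraries, 753 without fluoxetine libraries 2 and 4, 28 without vehicle libraries 1, 2 and 4, 103 without vehicle libraries 3, 5 and 6, and 773 to 1744 without 1 library. With replicate number as a block mossy cells gave 1095 and hippocampus 4802. Hippocampus gave 2093 with the shared spread and 1031 without vehicle libraries 1, 2 and 4, against 3172 without the other 3. Fewer libraries account for part of the loss, and for the rest the cause was not tested. The difference between mossy cells and hippocampus gave 23 with DESeq2 size factors, 33 with upper quartile, 23 at a mean CPM of at least 5, 109 with DESeq2, 17 with limma-voom, 116 with the block and 2 to 41 without 1 library. That between granule and mossy cells gave 43 at a mean CPM of at least 5, 276 with DESeq2, 1 with limma-voom, 0 with the block (1150 at an unadjusted p under 0.05) and 0 to 354 without 1 library. The block gave 10638 genes for mossy cells against hippocampus and 5340 for granule against mossy cells. With an estimated correlation 0 lists were called in granule cells, 1 in mossy cells, 0 in hippocampus, 6 in mossy cells against hippocampus, 6 in granule against mossy cells and 0 in each difference. Hippocampus and mossy-cell libraries were not paired in the main fits, though their permutations and regrouping for the difference in effect kept numbers in step. Same-number correlations were 0.069 to 0.201 with vehicle and 0.077 to 0.392 with fluoxetine, not all above the bound of 0.1 for pairs. Each library best matched its own number (6 of 6 and 7 of 7, mean 0.136 and 0.176 against −0.027 and −0.029 for other numbers). This points to pairs, though the design names none. The main fits ignore them (7 genes for the difference in effect, 116 with the block).

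Reversed values belong to genes that mostly had no call, and the cause was not tested. With limma-voom they were, in granule cells, Drd2 −0.41, S100a10 −0.11, Htr5b 0.41, Htr1a −0.09, Nmb −0.09, Adcyap1 0.079 and Pdyn −0.86, in mossy cells Ttr 0.85, Calb2 −0.06, Htr4 −0.037, Dsp −0.43 and Pdyn −0.19, in hippocampus Htr1a −0.022, and for the granule and mossy-cell difference Penk 0.36. With replicate number as a block they were Drd2 −0.23, Nmb −0.13, Adcyap1 0.41 and Pdyn −0.21 in granule cells and Calb2 −0.088, Dsp −0.29 and Pdyn −0.21 in mossy cells. With 1 surrogate variable they were Htr5b 0.22, Htr1a −0.003, Nmb −0.29 and Pdyn −0.21 in granule cells, Calb2 −0.007 and Dsp −0.23 in mossy cells and Htr1a −0.002 in hippocampus. Without granule-cell vehicle library 1 and fluoxetine library 4, Drd2 was −1.03 and Pdyn −0.18. With the Rn45s term Htr5b was 0.019, Nmb −0.019 and Adcyap1 0.024. With the GC content and length correction Dsp was −0.14 in mossy cells, Htr1a −0.058 in hippocampus and Calb1 0.50 in mossy cells against hippocampus. Without fluoxetine libraries 2 and 4 Htr1a was −0.035 and Htr4 −0.21 in mossy cells. Without vehicle libraries 1, 2 and 4 Ttr was 3.25, Calb2 −0.008 and Dsp −0.36 in mossy cells, and Clic6 1.83, Ttr 2.21 and Htr1a −0.016 in hippocampus. Without vehicle libraries 3, 5 and 6 Pdyn was −0.44 in mossy cells. Htr1a in hippocampus was −0.007 with no filter and −0.018 with the shared spread. With 1 library left out, granule-cell values ran from −1.24 to 1.76 for Drd2, −0.20 to 0.48 for Npy, −0.70 to 0.62 for Htr5b, −0.11 to 0.17 for Htr1a, −0.35 to 0.15 for Htr4, −0.97 to 0.57 for Nmb, −0.44 to 0.65 for Adcyap1 and −1.12 to 0.58 for Pdyn. In mossy cells they ran from −0.088 to 0.18 for Htr1a, −0.041 to 0.17 for Calb2, −0.049 to 0.20 for Htr4, −0.31 to 0.19 for Dsp and −0.76 to 0.46 for Pdyn, in hippocampus from −0.036 to 0.06 for Htr1a, and for the granule and mossy-cell difference from −0.17 to 0.20 for Penk.

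Of all values of named genes, the reversed ones included, in mossy cells 567 of 666 kept their direction and side of the threshold under settings other than a left-out library, 68 lost and 14 gained a call. In hippocampus 673 of 747 did, with 54 lost and 12 gained, and in granule cells 353 of 385, with 12 gained. With 1 library left out the same held for 488 of 546 values in mossy cells, 572 of 611 in hippocampus and 209 of 224 in granule cells. For the contrasts between sources 274 of 277 and 230 of 231 kept both under the other settings, and for the differences in effect 54 of 56 and 76 of 104. Depth, at 14.1 M counts or more per library, limits genes near 1 CPM, such as Pdyn and Tdo2 in mossy cells and Nmb in granule cells, which carry few counts. In granule cells the spread between libraries (a coefficient of biological variation of 50.3%, against 26.5% in mossy cells and 16.1% in hippocampus) limits what 4 against 4 can show.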

Other observations

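The predictions for the family tests were written before their results were seen, but the idea came from the list results in the same libraries, and the verdict on granule cells was changed afterwards as stated.

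Gene families outside the fixed lists moved apart by class, membrane and secreted proteins against the others. In mossy cells 64 of 244 solute carriers (Slc) rose and none fell (median 0.35), and 54 of 183 Tmem genes, 18 of 84 cadherins and protocadherins, 9 of 59 orphan receptors (Gpr) and 8 of 19 semaphorins rose as well. Proteasome subunits had 0 of 47 passing (median −0.15), and mitochondrial ribosomal proteins had 2 of 76 lower. In hippocampus 108 of 272 solute carriers rose and 10 fell, 72 of 202 Tmem genes rose and 7 fell, and 12 of 19 semaphorins rose. There 34 of 48 proteasome subunits fell and 1 rose (median −0.25), 45 of 76 mitochondrial ribosomal proteins fell, all 7 Cct chaperonin subunits fell, and 12 of 19 spliceosomal genes fell and 1 rose. No family had a called gene in granule cells.

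A hypothesis is that fluoxetine raises mRNAs translated at the endoplasmic reticulum, those of membrane and secreted proteins, relative to cytosolic, nuclear and mitochondrial ones, and 16 families chosen by name were used to test it. The difference of the family means was 0.45 in mossy cells (exact permutation p = 0.00175, two-sided, 1716 splits) and 0.51 in hippocampus (exact permutation p = 0.000583, the smallest these splits can give). In granule cells it was 0.37 (exact permutation p = 0.257, 70 assignments, smallest possible 0.0286). The bound written beforehand would have counted that p against the hypothesis in granule cells, but a missed p excludes nothing there, since with 8 libraries the most extreme of 35 splits alone can pass. Transcript GC content and length as the whole cause is argued against by a difference of 0.405 after the correction against 0.525 before it in mossy cells, both from edgeR log2 changes, where the 0.45 above is from mean log CPM. After the correction it was 0.437 in hippocampus and 0.228 in granule cells. Without fluoxetine libraries 2 and 4 the difference was 0.32 in mossy cells and 0.41 in hippocampus, and without vehicle libraries 1, 2 and 4 it was 0.46 and 0.53. Libraries of mossy cells and hippocampus may come from the same animals, so the 2 results are not shown to be independent. Whether RNA handling or ribosome recovery differed between treatments in a way that follows the place of translation could not be tested with these tables, so the hypothesis is consistent with the tests and not more.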
